A study of Mus musculus with 4 samples.

How the data were processed

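The data are single-nucleus RNA sequencing (snRNA-seq) of hippocampus from female mice that were 8 weeks old at the start. Per the labels, the mice were C57BL/6J wild type (WT) or carried the App NL-G-F knock-in, and were kept with or without voluntary wheel running over 10 weeks. This gives 4 groups with 1 library each. The treatment protocol in the labels names a running wheel for every sample, whereas the titles and the treatment label set 2 samples apart as without exercise, and the groups follow the titles. The labels do not say how many animals went into a library. The series design text also names an assay of open chromatin, which was not used here.

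Per the labels' protocols, nuclei were isolated from snap-frozen tissue and made into libraries with the 10x Chromium 3' v3.1 kit, which tags each captured RNA molecule with a unique molecular identifier (UMI) next to its polyadenylated end. The deposited values are counts, whole numbers of UMIs per gene and barcode, with no normalization. The matrix headers name Cell Ranger 5.0.1, whereas the submitters' processing notes name Cell Ranger 3.1.0 and the genome build mm10. Whether intron reads were counted, and whether strand was used, is not given in the sources used here. Of the 32285 gene identifiers in the files, 32158 matched GENCODE release M21, from which the coordinates on GRCm38 (mm10) were taken.

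The deposited matrices held 11514 barcodes for WT without exercise, 7203 for WT with exercise, 10453 for knock-in without exercise and 9466 for knock-in with exercise. Nuclei were kept with at least 500 genes, at least 1000 UMIs and under 5% mitochondrial UMIs. Doublets were scored per library against 2 simulated pairs per nucleus, and the highest-scoring share was left out at 0.8% per 1000 nuclei. That share was 8.98%, 5.50%, 8.07% and 7.57% in the same order. Of the simulated pairs, 59.8%, 40.5%, 56.2% and 53.9% scored above the limit, so some doublets were left in. The kept nuclei numbered 10213, 6508, 9278 and 8745.

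Kept counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 with a fixed seed gave 38 clusters. No integration across libraries was done. Clusters were named from markers of 25 classes, and 15 clusters stayed unnamed because they showed too few markers, markers of several classes, leading genes of another class, or low UMI counts. Class names mean that nuclei are like that type. Comparisons cover 7 classes: dentate granule, CA1, CA3 and inhibitory neurons, oligodendrocytes, astrocytes and microglia. Smaller classes are given where named.

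From the deposited counts, UMIs were summed per library and class and expressed per 1e+06 UMIs of the class (CPM). Each group had 1 library and nuclei are not replicates, so no test was made. No difference has a replicate check, and no p-value or count of changed genes is given. Sums carry exact Poisson 95% intervals, ratios the exact conditional binomial interval, and shares of nuclei the exact Clopper-Pearson interval. List medians carry an interval from 1000 Poisson redraws of the member counts. All of these cover counting error only and leave out differences between animals and between library preparations. Genotype without exercise and exercise in the knock-in share the library of the knock-in without exercise, so a value of that library enters both with opposite sign. The same holds for genotype with exercise and exercise in WT, which share the library of WT with exercise.

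Each list of genes was described by the median log2 ratio over members with at least 50 UMIs in the class, summed over the 4 libraries, where at least 5 members were measured. Its percentile among 10000 random lists of the same size, matched on mean CPM in 20 bins, describes these libraries and is not a test. A second percentile used random genes matched on both CPM and gene length. The lists, markers, filters and most alternatives were fixed before the data were examined. The 160 list medians reported, of 464 computed, were chosen after they were seen, as was the alternative minimum of 1200 UMIs. Scaling by the class total put the median of all genes in microglia at -0.12 for genotype without exercise, -0.16 for exercise in WT, 0.19 for exercise in the knock-in and 0.23 for genotype with exercise. It was -0.16 in astrocytes, -0.14 in CA3 neurons and -0.11 in oligodendrocytes for genotype without exercise, -0.10 in oligodendrocytes for exercise in WT and 0.13 in astrocytes for exercise in the knock-in. The other shifts in neurons stand beside their comparisons where they were at least 0.1 in size.

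The named genes follow a fixed rule for genotype without exercise, exercise in WT and exercise in the knock-in. A gene needed at least 100 UMIs over both libraries, at least 20 CPM in the higher library, and a class CPM there at least 0.5 times that over all its kept nuclei. Mitochondrial genes, ribosomal protein genes, Xist, Tsix and symbols that are Gm with digits or end in Rik were left out. The 2 highest and 2 lowest genes by the interval bound nearest to no difference were taken in each class with at least 50 nuclei in every library. Microglia fell short, with 48 nuclei in WT with exercise. Lgr6 in granule neurons and Col6a1 in CA3 neurons met the rule and are not given as results, since each leads a cluster of its class. Of each list, members named as examples are among the 2 highest or the 2 lowest by log2 ratio in the class and contrast. The value of 1 list member is not reported here.

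Counts with known ratios were simulated from Poisson distributions at the observed class totals, with no differences between animals or preparations. On these counts the interval held the true ratio for 95.4% of 13171 genes in granule neurons for exercise in the knock-in. The share was 96.3% of 4052 genes in microglia and 96.7% of 3876 genes in astrocytes for genotype without exercise. Of 100 simulated lists of 15 genes without a difference, drawn from 12972, 3857 and 3701 genes, 4%, 2% and 7% lay outside percentiles 2.5 to 97.5 in these 3 simulations. Their counting intervals held 0 in 100%, 100% and 98%, so these are wider than their nominal level.

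The alternatives were no doublet removal, at least 1000 genes or 1200 UMIs per nucleus, clustering resolutions 0.5 and 2.0, and 4000 variable genes. Others were TMM factors from edgeR 4.0.16, median-of-ratios factors as in DESeq2 1.42.0, and a total without mitochondrial genes and the 50 highest genes. Nuclei were also thinned to 1500 UMIs or weighted equally, and list members were restricted by UMIs or to genes with a class CPM at least that over all nuclei. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 were used.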

Results

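The hippocampus of female mice was profiled by snRNA-seq in a design that crosses genotype with voluntary running. App NL-G-F mice carry a humanised amyloid-beta sequence with disease mutations in their own App gene and form amyloid plaques. Each group had 1 library, so every value below is a description of that library, and the dependence of the exercise difference on genotype was not tested. Total UMIs were 91676884 for WT without exercise, 66573909 for WT with exercise, 64158446 for knock-in without exercise and 76111556 for knock-in with exercise. Median UMIs per deposited barcode were 6645, 7340, 5189 and 6483.5 in that order.

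App itself, the modified gene (ENSMUSG00000022892, chromosome 16, 84949685 to 85173766, GRCm38), stood at 517, 476, 485 and 524 CPM over all kept nuclei in the same order. A count next to the 3' end does not separate the knock-in allele from the mouse allele, so these levels do not check the genotype labels. Y-linked genes gave 6, 12, 15 and 5 UMIs and Xist, the X-inactivation RNA, 128317, 76701, 95813 and 130607. Malat1, an abundant nuclear RNA, took 3.23%, 6.04%, 9.51% and 3.34% of the kept UMIs. Ttr, the transthyretin gene of the choroid plexus, gave 442, 168, 11228 and 28 UMIs over all kept nuclei. Hbb-bs, a haemoglobin gene of red blood cells, gave 445, 854, 1360 and 45.

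Neurons of the dentate gyrus and Ammon's horn made up most kept nuclei. Granule neurons took 29.4% (28.5 to 30.3), 29.3% (28.2 to 30.5), 27.5% (26.6 to 28.4) and 31.7% (30.7 to 32.6) in the 4 libraries in the order above. CA1 neurons took 17.4%, 14.9%, 14.6% and 12.3%, CA3 neurons 8.09%, 7.99%, 6.80% and 6.34%, and inhibitory neurons 7.58%, 6.79%, 8.25% and 6.42%. Unnamed clusters held 11.0%, 16.3%, 16.0% and 14.8%. The lowest UMI count of a deposited barcode was 501, 500 and 504 in the first 3 libraries and 1199 in the knock-in with exercise, and this floor acts most on glia, whose nuclei hold few UMIs. Different clusters held a class in different libraries. Oligodendrocytes lay in cluster 4 for 91.0% and 91.2% of the WT libraries, in cluster 8 for 90.8% of the knock-in without exercise and in cluster 7 for 97.3% of the knock-in with exercise. Granule neurons of the knock-in with exercise lay in cluster 3 for 82.1%, and those of the others mostly in clusters 0 and 2. Clusters 3, 7 and 8 each came mostly from 1 library.

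**Figure D1:**
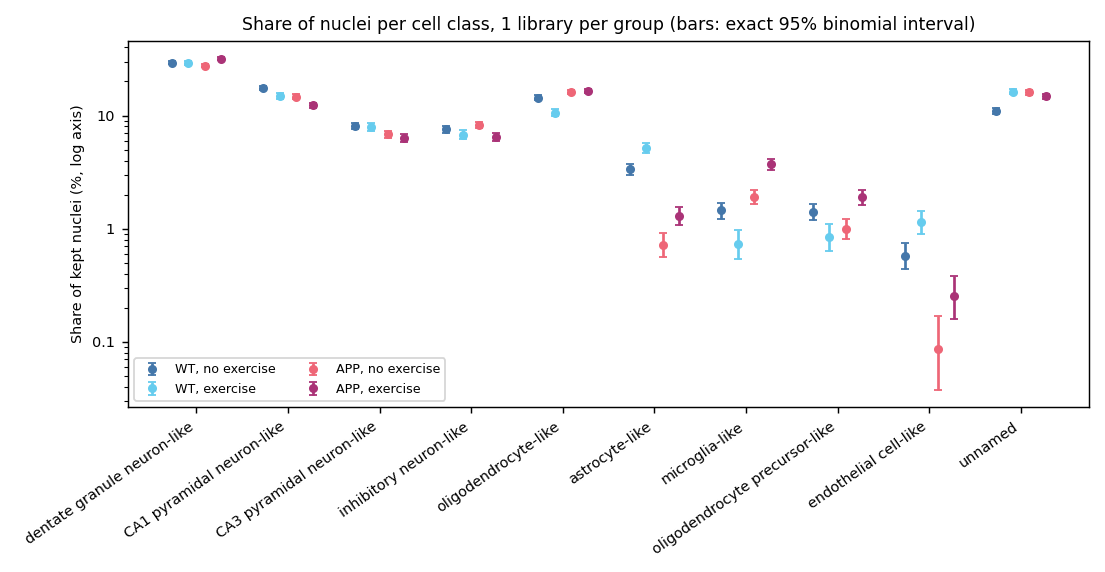
Share of kept nuclei (percent, log axis) per cell class in the 4 libraries, with exact binomial 95% intervals for counting error. Astrocytes were at 3.35% and 5.18% in the WT libraries and at 0.722% and 1.30% in the knock-in libraries.

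The comparison of genotypes without exercise asks how the App knock-in hippocampus differs from WT. Disease-associated microglia genes, a set switched on around amyloid plaques, were higher in the knock-in microglia, with a median log2 ratio of 1.26 (0.84 to 1.47) and 16 of 17 members higher. Csf1, a growth factor for microglia, stood at 45.1 CPM (23 UMIs) against 3.75 (2 UMIs), a log2 ratio of 3.59 (1.57 to 6.72), and Lilrb4a, an inhibitory receptor, at 39.2 against 3.75. Axl (0.39, -1.83 to 2.72) and B2m (-0.02, -0.75 to 0.71) were the lowest members. The list median lay at percentile 100 of the random lists and was 1.38 relative to the median of all genes. It ranged from 0.67, after thinning to 1500 UMIs, to 1.33 over 14 alternatives. In the same microglia oligodendrocyte markers stood at 884 against 469 CPM and astrocyte markers at 173 against 522. Homeostatic microglia genes, several of them markers that named the class, had a median of -0.28 (-0.43 to 0.01), which was -0.59 with no doublets left out, -0.48 at resolution 2.0 and -0.60 with 4000 variable genes. Complement genes had 0.87 (0.47 to 1.19), or 0.41 after thinning, with C1qa, itself a marker of the class, at 345 against 141 CPM and Itgam, an integrin subunit, at 131 against 212. Glial Alzheimer risk genes stood at -0.15 (-0.49 to 0.01) and interferon response genes at -0.12 (-0.63 to 0.35). Microglia were 1.92% (1.65 to 2.22) of nuclei in the knock-in and 1.45% (1.23 to 1.70) in WT, a log2 ratio of 0.40 that was -0.14 with at least 1000 genes per nucleus.

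Other glia also differed between these libraries. Astrocytes were 0.722% (0.560 to 0.916) of nuclei in the knock-in and 3.35% (3.01 to 3.72) in WT, a log2 ratio of -2.21. Endothelial nuclei were at 0.0862% (8 nuclei) against 0.578%. Oligodendrocytes were at 16.2% against 14.4%, a ratio of 0.17 that turned to -1.54 with at least 1000 genes per nucleus and to -0.21 with at least 1200 UMIs. Disease-associated oligodendrocyte genes had a median of 0.55 (0.11 to 0.88) with 8 of 10 higher, between clusters 8 and 4, -0.02 with at least 1000 genes per nucleus and 0.03 over members with at least 200 UMIs. Klk6, a secreted protease, stood at 18.5 against 2.46 CPM and H2-D1, an antigen-presenting molecule, at 38.8 against 11.6. C4b, a complement component, was lower (-1.53, -2.32 to -0.80). Myelin genes, of which several lead the oligodendrocyte clusters, had a median of 0.26 (0.20 to 0.31). In astrocytes, the disease-associated list was at -0.68 (-1.12 to -0.16) and the homeostatic list at -0.22 (-0.44 to -0.15), and the former turned to 0.14 at resolution 2.0. Astrocyte markers stood at 8306 CPM in these 67 knock-in nuclei against 12388 in 342 WT nuclei.

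In neurons, genes of oxidative phosphorylation (OXPHOS), which make the mitochondrial respiratory chain, and of the cytosolic ribosome were higher in the knock-in without exercise. In granule neurons the OXPHOS median was 0.66 (0.56 to 0.71) with 33 of 38 higher, and the ribosomal median 0.65 (0.58 to 0.70) with 35 of 36 higher. Cox7c, a subunit of cytochrome oxidase, stood at 120 against 40.4 CPM. The UMIs of both lists per granule nucleus were 16.3 against 15.1, whereas all UMIs per granule nucleus were 4894 against 6685, and at resolution 2.0 those of both lists were 16.97 against 17.93. Among members at least as high in granule neurons as over all nuclei, the medians were 0.05 and 0.28, and with 4000 variable genes they were 0.43 and 0.38. In CA1, CA3 and inhibitory neurons the OXPHOS medians were 0.50, 0.46 and 0.60 and the ribosomal ones 0.56, 0.54 and 0.61. In oligodendrocytes, compared between clusters 8 and 4, they were 1.0 and 1.02, in astrocytes 0.76 and 0.28, and in microglia 0.59 and 0.88. The astrocyte ribosomal median lay at percentile 3.97 of lists matched on gene length as well. UMIs of both lists per nucleus were 18.7 against 16.1 in CA1, 23.8 against 20.7 in CA3 and 22.2 against 20.04 in inhibitory neurons. They were 10.6 against 7.09 in oligodendrocytes, 14.1 against 12.5 in astrocytes and 14.04 against 10.5 in microglia, and all UMIs per nucleus were lower in the knock-in in each of these classes. Glycolysis genes had a median of 0.31 (0.15 to 0.41) in granule neurons and neurogenesis genes 0.52 (0.30 to 0.72), whereas voltage-gated ion channels had -0.33 (-0.39 to -0.23). In the same granule neurons CA3 markers stood at 565 against 715 CPM and inhibitory markers at 75.8 against 113, and log2 ratios had a Spearman correlation with gene length of -0.29 across genes. Genes of the glutamatergic synapse (-0.24), the GABAergic synapse (-0.03), amyloid precursor processing (-0.13) and the mitochondrial genome (-0.02) completed the granule neuron lists, and immediate early genes had -0.15 (-0.36 to 0.07). The GABAergic median turned to 0.05 with a total without mitochondrial and the 50 highest genes, and the mitochondrial genome median was -0.96 with no doublets left out and -1.02 with 4000 variable genes.

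Tmem163, which codes for a zinc transporter of synaptic vesicles, ranked lowest by the rule of size in the 4 neuron classes compared. In granule neurons it stood at 2.08 CPM (26 UMIs) in the knock-in and 167 CPM (3352 UMIs) in WT, a log2 ratio of -6.33 (-6.94 to -5.77), and in CA1 neurons at 10.8 against 183 CPM. With exercise it was at 3.99 CPM in knock-in and 104 in WT granule neurons. Tmem163 (ENSMUSG00000026347) lies on chromosome 1 from 127486546 to 127679548 and overlaps Mgat5 on the other strand, so its count is uncertain. Rgl2, which acts on Ral GTPases (ENSMUSG00000041354, chromosome 17, 33929543 to 33937687), stood at 6.85 against 38.2 CPM in CA1 neurons (-2.48, -2.86 to -2.12). Rabif in CA3 neurons was at -2.32 (-2.79 to -1.88). Higher in the knock-in were Malat1 in CA1 neurons (93421 against 29997 CPM, 1.64), Trmt10a in granule neurons (1.94, 1.64 to 2.25), Smim19 in CA1 neurons (1.88), Rsf1os1 in CA3 neurons (2.05) and Tmem181a in inhibitory neurons (2.07). Trmt10a, Smim19, Rsf1os1 and Tmem181a overlap named genes on the other strand and are uncertain, and Tmem181a also has near-identical copies. In oligodendrocytes Ttr stood at 263 against 8.80 CPM (4.90, 4.32 to 5.54), while over all kept nuclei it stood at 207 against 5.83. Adamts2 was at 8.12 against 65.8 in oligodendrocytes (-3.02).

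The comparison of WT libraries asks what running went with in healthy hippocampus. Genes of the unfolded protein response, which handle misfolded protein in the endoplasmic reticulum, were lower with exercise. In CA1 neurons the median was -0.53 (-0.66 to -0.37) with 1 of 17 members higher, at percentile 0.01. Calr, a calcium-binding chaperone, stood at 19.6 against 45.0 CPM (-1.20, -1.43 to -0.97) and Atf6, a stress sensor, at 129 in both. Medians were -0.39 in granule, -0.47 in CA3 and -0.26 in inhibitory neurons, and -0.36 in oligodendrocytes. Heat shock genes were at -0.44 (-0.51 to -0.30) in CA1 neurons, -0.26 in granule, -0.44 in CA3 and -0.28 in inhibitory neurons, with Hspa8, a chaperone, at 24.5 against 41.8 CPM in CA1 neurons. Scaling by the class total put the median of all genes at -0.18 in CA1, -0.18 in CA3, -0.12 in granule and -0.12 in inhibitory neurons in this comparison. Relative to it the unfolded protein response list was at -0.35 and the heat shock list at -0.26 in CA1 neurons. Log2 ratios also followed gene length, with Spearman correlations across genes of 0.20 in granule, 0.28 in CA1, 0.36 in CA3 and 0.31 in inhibitory neurons. In CA1 neurons oligodendrocyte markers stood at 87.5 with against 137 CPM without exercise, and in granule neurons inhibitory markers at 73.2 against 113. In CA3 neurons granule markers stood at 148 against 76.7 and oligodendrocyte markers at 207 against 305, and in inhibitory neurons the latter at 206 against 172. Among length-matched lists the unfolded protein response lay at percentile 0.21, 0.07, 2.14 and 26.8 in that order and heat shock genes at 19.1, 1.81, 7.64 and 28.2.

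Circadian clock genes were lower with exercise in WT granule neurons, with a median of -0.44 (-0.50 to -0.28) and 2 of 16 higher, and in CA1 neurons, with -0.40 (-0.49 to -0.25). Per3, a period gene, had a log2 ratio of -1.03 in CA1 neurons and Arntl, the core activator, stood at 104 against 82.5 CPM. Relative to all genes these medians were -0.31 and -0.22, and TMM scaling gave -0.24 in CA1 neurons. Clock medians were -0.19 in CA3 neurons, -0.09 in inhibitory neurons and -0.16 in oligodendrocytes. Per3 and Arntl went in opposite directions in CA1 neurons, so the list median does not measure the state of the clock. Time of day at collection was not among the sample values used here. With 1 library per group it cannot be told apart from group. Immediate early genes, which follow neuronal firing, were lower in CA1 neurons (-0.54, -0.66 to -0.32), with Egr4 at 2.34 against 5.09 CPM and Nr4a1 at a log2 ratio of 0.10, and this median was -0.23 with 4000 variable genes. They stood at -0.22 in granule, -0.25 in CA3 and -0.03 in inhibitory neurons. Bdnf, the neurotrophin most studied with running, was at 80.9 against 59.1 CPM in granule neurons (0.45, 0.33 to 0.57), while its neurotrophic and exercise-linked list was at -0.20 (-0.30 to -0.07) and the delayed activity-regulated list at -0.07 (-0.18 to 0.10). Vgf, a neuropeptide precursor, was at 5.01 against 10.5.

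Among other lists in WT granule neurons, mitochondrial genome transcripts were at -0.85 (-1.04 to -0.71), ribosomal genes at -0.33 (-0.41 to -0.27), OXPHOS genes at -0.17 (-0.21 to -0.12) and amyloid precursor processing genes at -0.25 (-0.34 to -0.20). Medians were -0.27 for cholesterol synthesis, -0.18 for glycolysis, -0.16 for glucocorticoid response, -0.14 for neurogenesis, -0.04 for glutamatergic synapse and -0.02 for GABAergic synapse genes, where the median of all genes was -0.12. With median-of-ratios factors the OXPHOS median was -0.05, the ribosomal one -0.21 and the glutamatergic one 0.09, and the glucocorticoid one turned to 0.01 after thinning. Ribosomal medians were -0.38 in CA1, -0.47 in CA3 and -0.36 in inhibitory neurons, 0.12 in oligodendrocytes and -0.71 in microglia. Among lists matched on gene length as well, the ribosomal median lay at percentile 9.66 in granule, 39.3 in CA1, 24.8 in CA3 and 27.8 in inhibitory neurons. With 4000 variable genes the CA1 value turned to 0.15, and at resolution 2.0 the microglia value turned to 0.22. OXPHOS medians were -0.23 in CA1, -0.42 in CA3 and -0.16 in inhibitory neurons, 0.12 in oligodendrocytes and -0.62 in microglia. In WT astrocytes, disease-associated genes were lower with exercise (-0.73, -1.22 to -0.61, 0 of 10 higher), with Apoe, a lipid carrier, at 1434 against 5153 CPM (-1.85, -1.94 to -1.75). Apoe was also lower in 5 of 5 other classes. Oligodendrocyte markers in these astrocytes stood at 1069 CPM with exercise and 676 without, and Mbp, a myelin gene, at a log2 ratio of 1.60 that turned to -0.26 at resolution 2.0. Homeostatic astrocyte genes were at -0.23 (-0.36 to -0.08). Ribosomal (0.88, 0.76 to 1.02) and OXPHOS genes (0.30) were higher there, but both were at -0.03 at resolution 2.0. Blood-brain barrier and angiogenesis genes were higher in 16 of 16 members in endothelial nuclei, with a median of 0.25 (0.15 to 0.45) over 74 and 59 nuclei. Several genes of this list, such as Flt1 and Cldn5, are markers that named the class, so the count is not independent of the naming. The median of all genes was not computed for endothelial nuclei.

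Glial shares in WT also differed. Microglia were 0.738% (0.544 to 0.977) with exercise and 1.45% without, a log2 ratio of -0.97, astrocytes 5.18% against 3.35% (0.63), and oligodendrocytes 10.6% against 14.4% (-0.44), which was -0.85 with at least 1000 genes per nucleus. Oligodendrocyte precursors were 0.845% against 1.41%, a ratio of -0.74 that turned to 0.22 with 4000 variable genes, and 0 of 14 genes of oligodendrocyte differentiation were higher in them (median -0.44, -0.60 to -0.31), which was -1.75 with 4000 variable genes and -0.10 after thinning. Pdgfra, Cspg4 and Vcan of that list are markers that named the class. The class held 55 nuclei of WT with exercise, or 117 with 4000 variable genes. Myelin genes were at -0.04 and disease-associated oligodendrocyte genes at 0.02 in oligodendrocytes, of which cluster 4 held 91.0% and 91.2%. The 48 microglia of the exercised WT library had microglia markers at 1888 CPM (1738 to 2048) against 3274 and granule neuron markers at 1298 against 972. In them the disease-associated list was at -1.06 (-1.53 to -0.59), the homeostatic list at -0.74, complement at -1.0 and interferon response at -0.98. With no doublets left out, the homeostatic, complement and interferon lists turned to 0.04, 0.07 and 0.37. The share ratio was -1.58 at resolution 2.0. With 27 nuclei at resolution 2.0 the disease-associated list was at -0.07 and the interferon list at 0.25.

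By the rule of size, Malat1 was higher with exercise in WT neurons (60432 against 32023 CPM in granule neurons, 0.92) and Gas5, a growth-arrest RNA that hosts small nucleolar RNAs, lower. Gas5 (ENSMUSG00000053332, chromosome 1, 161034422 to 161038539) stood at 37.2 against 98.9 CPM in granule neurons (-1.41, -1.55 to -1.27) and at -1.56 in CA1, -1.72 in CA3 and -1.65 in inhibitory neurons, and it overlaps Zbtb37 on the other strand. Sst, the somatostatin gene, was at 18.7 against 89.2 CPM in inhibitory neurons (-2.26, -2.58 to -1.94). It was also lower in 4 of 5 other classes, so the difference is not particular to inhibitory neurons. Ssbp4 in granule neurons was at -1.22 and Mid1 in CA1 neurons at -1.66. Lhfp (1.48) in granule neurons, Diras2 (0.92) in CA1, Luzp2 (0.70) in CA3 and Cadps2 (0.73) in inhibitory neurons were higher. In astrocytes Myoc was lower (29.4 against 391 CPM, -3.73), and Fth1, the ferritin heavy chain, was higher (1.47, 1.32 to 1.63). Fth1 has processed copies in the genome and is uncertain.

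The comparison of knock-in libraries asks what running went with in knock-in hippocampus. OXPHOS and ribosomal genes were lower with exercise in granule neurons, with medians of -1.25 (-1.28 to -1.10, 5 of 38 higher) and -1.30 (-1.38 to -1.21, 1 of 36 higher), between cluster 3 and clusters 0 and 2. Ndufa4 was at a log2 ratio of -2.08 and Rpl7 at 7.58 against 27.2 (-1.84), while Sdhb, a subunit of complex II, was at 40.7 against 33.6. Among members at least as high in granule neurons as over all nuclei the medians were -0.45 and -0.80. OXPHOS medians were -0.92 in CA1, -0.83 in CA3, -0.98 in inhibitory neurons, -0.97 in microglia, -0.39 in astrocytes and -2.02 in oligodendrocytes, compared there between clusters 7 and 8. Ribosomal medians were -0.95, -0.90, -1.08, -1.17, 0.14 and -1.97. At resolution 2.0 the astrocyte medians were -1.41 and -1.58 for the OXPHOS and ribosomal lists and the microglia ones -1.45 and -1.80. Mitochondrial genome transcripts in granule neurons were at -1.26 (-1.38 to -1.11). The UMIs of both lists per nucleus were 4.34 fewer with exercise in granule neurons, from 16.3 without it, and 6.29 against 10.6 in oligodendrocytes, whereas all UMIs per nucleus were 7240 against 4894 and 2969 against 1474. In astrocytes they were 23.0 with exercise against 14.1, but 8.45 against 12.7 at resolution 2.0. The knock-in library without exercise also stands in the genotype comparison without exercise, where both lists were higher.

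**Figure D2:**
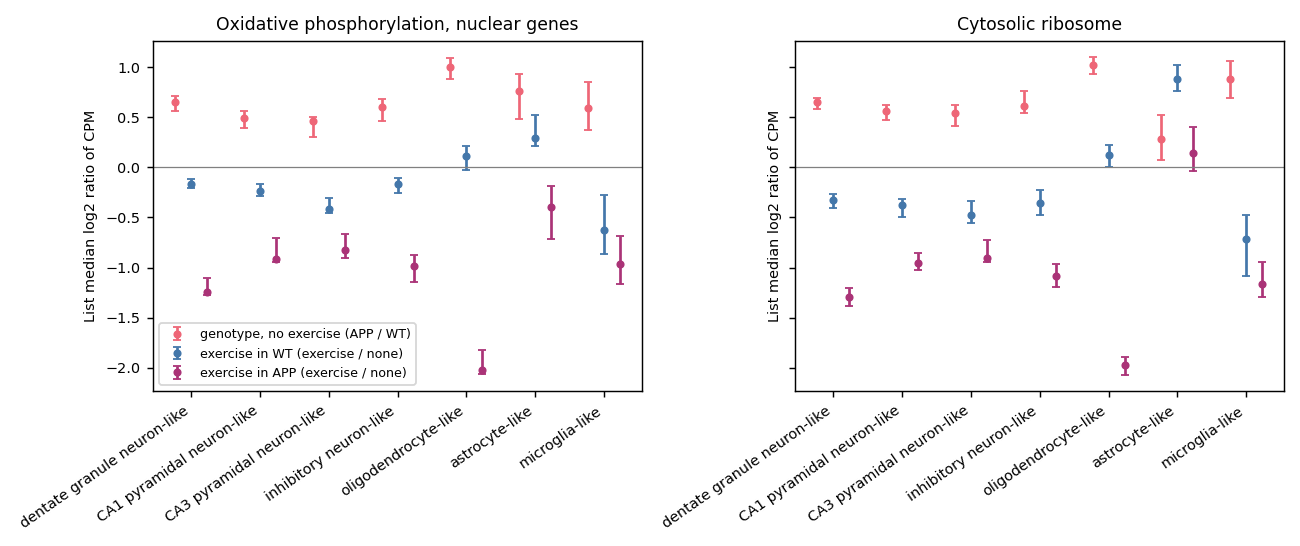
Median log2 ratio of CPM over the OXPHOS list (left) and the ribosomal list (right) in 7 classes, for 3 contrasts, with bars for the counting interval. For exercise in the knock-in the OXPHOS medians run from -0.39 in astrocytes to -2.02 in oligodendrocytes.

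Interferon response genes were higher with exercise in knock-in microglia, with a median of 2.11 (1.78 to 2.63) and 6 of 6 measured members higher, at percentile 100. The list has 18 genes in the files, and a member needed at least 50 UMIs in the class over the 4 libraries. The knock-in held 325 microglia with and 178 without exercise, so a gene high with exercise passes this minimum more readily. Oasl2, an antiviral protein, stood at 56.9 against 5.88 CPM (3.27, 1.66 to 5.59), Rnf213, a ubiquitin ligase, at 172 against 27.4, and Trim30a at 170 against 72.5. The median was 1.92 relative to all genes and ranged from 1.47, with no doublets left out, to 2.77 over 13 alternatives. Among markers of other classes in the same microglia, astrocyte markers stood at 397 against 173 CPM, CA3 markers at 656 against 339 and inhibitory markers at 472 against 302, whereas CA1 markers stood at 99.4 against 199.97. In CA1 neurons 5 of 5 measured members were higher (1.02, 0.88 to 1.63), and the medians were 0.83 in inhibitory neurons, 0.52 in oligodendrocytes, 0.42 in CA3 and 0.41 in granule neurons, where the inhibitory one turned to -0.17 without a UMI minimum. In the same CA1 neurons inhibitory markers stood at 121 against 24.9 CPM, granule markers at 145 against 73.9 and CA3 markers at 441 against 268. In oligodendrocytes CA3 markers stood at 1186 against 611, and in inhibitory neurons at 1096 against 733, where the inhibitory markers themselves were at 5281 against 8115. Disease-associated microglia genes were at 0.33 (0.08 to 0.54) with 10 of 18 higher, and this ranged from -0.34, with no doublets left out, to 0.88, with at least 1000 genes per nucleus. Axl, a receptor kinase for dying cells, was at 70.5 against 9.80 CPM (2.85) and Apoe at 173 against 729 (-2.08). Complement genes were lower (-1.03, -1.40 to -0.68), with C1qa at 66.8 against 345 CPM. Their median was -1.84 with no doublets left out, -1.98 at resolution 2.0 and -1.69 with 4000 variable genes. Homeostatic genes were at 0.16 (-0.03 relative to all genes) and Alzheimer risk genes at 0.04. Under the same 3 alternatives these turned to -0.59, -0.68 and -0.38 for homeostatic and -0.69, -0.73 and -0.51 for Alzheimer risk genes.

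**Figure D3:**
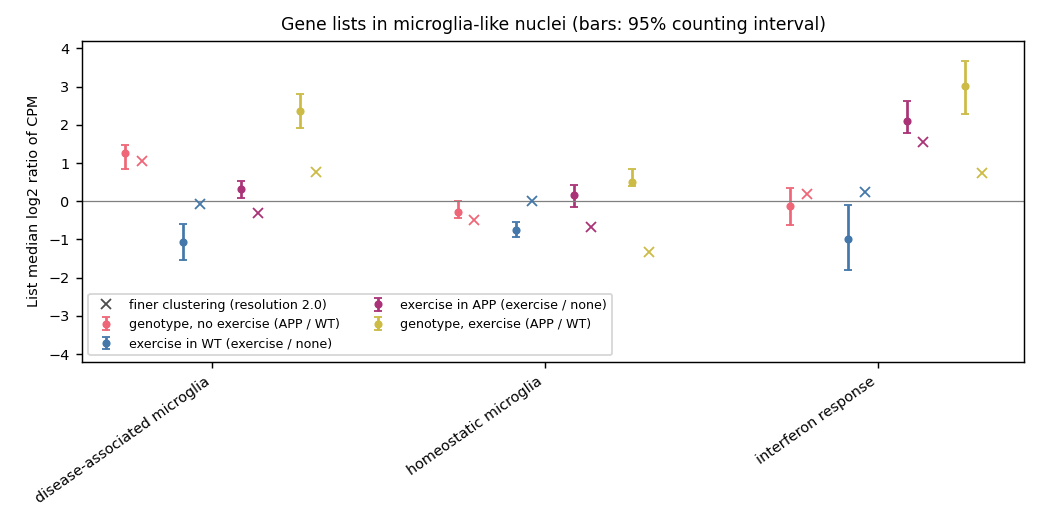
Median log2 ratio of CPM for 3 lists in microglia-like nuclei in the 4 contrasts, with counting intervals, and crosses for the finer clustering. The interferon list is at 2.11 for exercise in the knock-in and 1.55 with the finer clustering.

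The median of the clock list was higher with exercise in knock-in neurons. The medians were 0.40 (0.32 to 0.50) in granule, 0.59 (0.42 to 0.66) in CA1, 0.53 in CA3 and 0.48 in inhibitory neurons and 0.20 in oligodendrocytes, with Per1 at 22.0 against 7.29 CPM in granule neurons and Per2 at 61.1 against 29.7 in CA1 neurons. In the same neurons inhibitory markers stood at 205 against 75.8 CPM in granule, 121 against 24.9 in CA1 and 93.1 against 42.4 in CA3 neurons, but at 5281 against 8115 in inhibitory neurons themselves. CA3 markers stood at 894 against 565 in granule neurons. Scaling by the class total put the median of all genes at 0.14 in CA1, 0.17 in CA3 and 0.13 in inhibitory neurons, and relative to it the CA1 clock list was at 0.46. Among members at least as high in granule neurons as over all nuclei the granule median was 0.10, and the oligodendrocyte one turned to -0.02. Voltage-gated channels were higher in granule neurons (0.42, 0.33 to 0.59, 21 of 25), compared between cluster 3 and clusters 0 and 2, at 0.34 relative to all genes. Kcnq5, at 244 against 71.0 CPM, is also among the leading genes of CA3 cluster 6, and CA3 markers in granule neurons stood at 894 against 565. Log2 ratios in granule neurons had a Spearman correlation with gene length of 0.27 across genes, and the channel list lay at percentile 99.5 of length-matched lists. Immediate early genes were at -0.56 (-0.74 to -0.28) in CA1 and -0.49 in CA3 neurons, where Nr4a1 stood at 48.0 against 20.7 and Junb at 8.85 against 37.2 CPM in CA1 neurons, and the CA1 median was -0.01 after thinning. They were at -0.22 in granule neurons, which turned to 0.42 after thinning, and -0.01 in inhibitory neurons. Unfolded protein response genes were at -0.31 in granule, -0.25 in CA1, -0.14 in CA3 and -0.31 in inhibitory neurons and -1.04 in oligodendrocytes, and heat shock genes at 0.00 in CA1 neurons.

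Neurotrophic and exercise-linked genes were at 0.12 (0.08 to 0.36) in knock-in granule neurons, with Vegfa, a vascular growth factor, at 9.13 against 3.04 CPM, and at 0.68 (0.27 to 0.78) in CA3 neurons, where Bdnf was at 34.5 against 57.6. In WT CA3 neurons that list was at -0.02. In the knock-in CA3 neurons inhibitory markers stood at 93.1 CPM with against 42.4 without exercise and CA1 markers at 34.4 against 19.0. The CA3 markers themselves stood at 3856 against 2986. Delayed activity-regulated (0.07), glutamatergic synapse (0.11), GABAergic synapse (-0.14), glucocorticoid response (-0.21), glycolysis (-0.25) and neurogenesis (-0.36) lists completed the granule neurons. With a total without mitochondrial and the 50 highest genes, the neurotrophic and glutamatergic medians turned to -0.01 and -0.02. In astrocytes glucocorticoid response genes were at 0.64 (0.08 to 1.35), with Zbtb16 at 255 against 36.0 CPM, disease-associated genes at 0.32 and homeostatic genes at -0.22, which turned to 0.20 with no doublets left out. The glucocorticoid median was 1.92 after thinning. In the same astrocytes granule neuron markers stood at 468 CPM with exercise and 166 without, CA3 markers at 486 and 180, and oligodendrocyte markers at 1275 and 606. In WT astrocytes glucocorticoid response genes were at -0.52. Myelin genes were lower in oligodendrocytes (-0.64, -0.70 to -0.57), and disease-associated oligodendrocyte genes were at -0.24, which turned to 0.31 with at least 1000 genes per nucleus. The markers that named these oligodendrocytes, several of them myelin genes, stood at 10692 CPM with against 13068 without exercise. CA3 markers in the same nuclei were higher with exercise, as given above. Shares with exercise were 3.72% (3.33 to 4.13) against 1.92% for microglia, 1.30% against 0.722% for astrocytes, 1.90% against 1.0% for oligodendrocyte precursors, whose differentiation list was at 0.00, and 16.5% against 16.2% for oligodendrocytes. The oligodendrocyte ratio of 0.02 was 2.04 with at least 1000 genes per nucleus and 0.43 with at least 1200 UMIs, and the microglia ratio of 0.95 was 1.68 with at least 1000 genes.

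**Figure D4:**
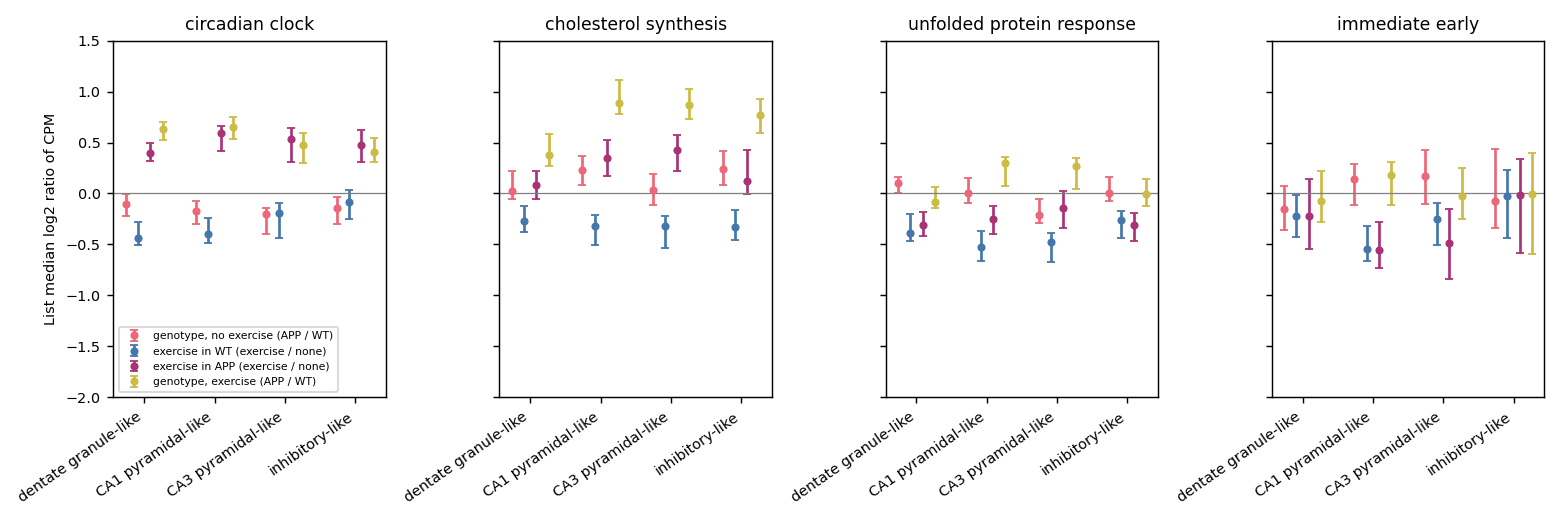
Median log2 ratio of CPM for 4 lists in 4 neuron classes and 4 contrasts, with counting intervals. The clock medians in CA1 neurons are -0.40 for exercise in WT and 0.59 for exercise in the knock-in.

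Catspere1, a sperm calcium channel subunit gene (ENSMUSG00000102483, chromosome 1, 177808550 to 177962233), ranked highest with exercise in the knock-in in the 4 neuron classes. In granule neurons it stood at 28.2 CPM (565 UMIs) against 0.160 (2 UMIs), a log2 ratio of 7.46 (5.60 to 10.51), and it was at 0.498 and 0.508 CPM in the WT libraries. In CA1 neurons Catspere1 stood at 59.2 against 2.06 CPM. P2ry14, a nucleotide-sugar receptor (ENSMUSG00000036381, chromosome 3, 59113855 to 59153618), was lower at 27.2 against 284 CPM in granule neurons (-3.38, -3.52 to -3.25) and lies within Med12l on the other strand. Nrg3os (-3.35 in CA1), Far1os (-3.48 in CA1) and Rsf1os1 (-3.60 in granule neurons) were lower, and are uncertain as antisense genes. Rgl2 was higher in CA1 neurons (34.2 against 6.85 CPM, 2.32), Cpne9 in granule neurons (2.98), Prkcd, a protein kinase C, in CA3 neurons (3.69) and Tmem86b in inhibitory neurons (2.53). Over all kept nuclei Prkcd stood at 9.83 against 3.44 CPM. Cluster 6 held 77.6% of the CA3 nuclei with exercise and 59.0% without it, so the make-up of that class also differed. In oligodendrocytes Ttr was at 0.935 against 263 CPM, and over all kept nuclei at 0.435 against 207. Ubb, a ubiquitin gene, was at 46.1 against 516 in oligodendrocytes (-3.49), whereas Kcnip4 (2.60) and Lrrtm4 (1891 against 333 CPM), both abundant in neurons, were higher.

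The comparison of genotypes with exercise uses the remaining pair of libraries. Cholesterol synthesis genes were higher in the knock-in in CA1 (0.89, 0.78 to 1.12), CA3 (0.87) and inhibitory neurons (0.77), in 18 of 18 members in each, and in granule neurons (0.38, or 0.19 with TMM factors). Msmo1, a sterol oxidase, stood at 21.4 against 7.01 CPM in CA1 neurons. Without exercise the CA1 median was 0.23 (0.09 to 0.36), and for exercise in WT it was -0.32 in CA1, -0.32 in CA3 and -0.33 in inhibitory neurons. Relative to the median of all genes these WT values were -0.14, -0.14 and -0.21. They share the library of WT with exercise with the genotype comparison with exercise, with opposite sign, so they are not separate evidence. Scaling put the median of all genes at 0.27 in CA1, 0.24 in CA3, 0.22 in inhibitory and 0.19 in granule neurons, and relative to it the CA1 cholesterol list was at 0.62. In the same CA1 neurons oligodendrocyte markers stood at 201 against 87.5 CPM, granule markers at 145 against 57.6 and inhibitory markers at 121 against 36.8. Inhibitory markers stood at 93.1 against 34.4 in CA3 and 205 against 73.2 in granule neurons, but at 5281 against 7613 in inhibitory neurons themselves, where oligodendrocyte markers were at 246 against 206. Clock genes were at 0.66 in CA1 and 0.63 in granule neurons, against -0.17 and -0.11 without exercise, where the granule value turned to 0.04 over members at least as high there as over all nuclei. In microglia, disease-associated genes were at 2.37 (1.91 to 2.82), interferon genes at 3.02 (2.29 to 3.68) and homeostatic genes at 0.51, which became 0.78, 0.75 and -1.33 at resolution 2.0. WT with exercise had 48 microglia, and microglia markers stood at 3736 CPM in the knock-in against 1888 in them. Oligodendrocyte markers in these microglia stood at 866 against 373, astrocyte markers at 397 against 204 and CA3 markers at 656 against 444, whereas CA1 markers stood at 99.4 against 178. Interferon genes in CA1 neurons were at 1.05, disease-associated oligodendrocyte genes at 0.55 between clusters 7 and 4 (0.02 over members with at least 200 UMIs), and microglia made up 3.72% against 0.738% of nuclei.

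Of 14 correlations computed across genes, the log2 ratios of exercise in WT and in the knock-in, which share no library, had Pearson correlations of -0.20 in granule, -0.24 in CA1, -0.24 in CA3 and -0.14 in inhibitory neurons, -0.25 in oligodendrocytes, -0.12 in astrocytes and -0.08 in microglia. The genotype ratios without and with exercise, which share no library either, gave -0.39, -0.38, -0.43, -0.41, -0.49, -0.17 and 0.05. Genes are not independent replicates, so these values describe the libraries alone.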

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

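The tests of gene length were chosen before their results were seen, whereas those of free RNA, of a few genes taking most counts and of neuronal RNA in microglia were chosen after. The first 2 of these were split between astrocytes and the other classes, and by resolution in astrocytes, once values were known. The test of neuronal RNA replaced one at resolution 2.0, where neuron markers in the microglia class stayed at 2022 to 2504 CPM, against 2008 to 2359 in the main class, so that such RNA was not removed.

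With scaling by the class total, several results went in opposite directions in the groups compared, which drew attention to them, and none of these differences was tested. The exercise difference in the knock-in minus that in WT, as log2 ratios, was 0.99 for clock genes in CA1 neurons, 0.73 in CA3 neurons and 0.84 in granule neurons. For interferon genes in microglia it was 3.08, for disease-associated microglia genes 1.38 and for glucocorticoid response genes in astrocytes 1.15. At resolution 2.0 the exercise differences in WT and in the knock-in had the same sign for interferon genes (0.25 and 1.55) and disease-associated microglia genes (-0.07 and -0.31), and WT with exercise had 48 microglia, or 27 at resolution 2.0. Ribosomal genes in oligodendrocytes had -2.09 and OXPHOS genes in astrocytes -0.69, for which the WT value was -0.03 at resolution 2.0. In granule neurons the neurotrophic list had 0.33 and the glutamatergic synapse list 0.15, and with a total without mitochondrial and the 50 highest genes their values in the knock-in were -0.01 and -0.02. Relative to the median of all genes, clock medians for exercise in WT and in the knock-in were -0.22 and 0.46 in CA1 neurons. They were -0.01 and 0.37 in CA3 and -0.31 and 0.31 in granule neurons. In granule neurons the neurotrophic medians were then -0.08 and 0.04, and the glutamatergic ones 0.09 and 0.02, of the same sign. Shares of nuclei gave 1.93 for microglia, 1.66 for oligodendrocyte precursors and -0.88 for subicular or cortical excitatory neurons. With 4000 variable genes the WT share ratio of oligodendrocyte precursors was 0.22.

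The genotype difference with exercise minus that without exercise was 0.83 for clock genes in CA1 neurons and 0.74 in granule neurons. In granule neurons the clock value without exercise turned to 0.04 over members at least as high there as over all nuclei. For shares it was 0.21 in granule neurons, whose ratio without exercise was 0.06 with at least 1000 genes per nucleus, and for oligodendrocyte precursors (1.66) and subicular or cortical neurons (-0.88) it equals the exercise value, being made of the same 4 shares. Nuclei in unnamed clusters, which enter no class comparison, made up 11.0% of WT without exercise, 16.3% of WT with exercise, 16.0% of the knock-in without exercise and 14.8% of the knock-in with exercise.

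OXPHOS genes were lower in the knock-in with exercise than without it in 7 of 7 classes and ribosomal genes in 6 of 7, with astrocytes at 0.14. Outside astrocytes, a trend with gene length as the whole cause is argued against by medians below percentile 2.5 of length-matched lists in 6 of 7 classes for each list (55.4 and 99.97 in astrocytes), and a few genes taking most counts by an OXPHOS median of at most -0.96 under other scalings, and by an upper bound of -0.76 in astrocytes at resolution 2.0. More free RNA without exercise may account for the 6 other classes, where the UMIs of both lists per nucleus were higher without exercise by 3.17 to 5.74 and the highest difference was 1.81 times the lowest, and for astrocytes at resolution 2.0, with a difference of 4.24 (3.21 to 5.27). A fall by a like proportion in each class could also give this, since the levels without exercise, given above, had a like spread across these classes. The spread of the differences therefore does not favour free RNA over lower levels with exercise. In the main astrocyte class scaling (-0.31, between both predictions) and free RNA (-8.96, -10.2 to -7.70) cannot be told apart from lower levels, since other classes' markers there gave 26.1 UMIs per nucleus with exercise against 10.8 and both lists were at -1.41 and -1.58 at resolution 2.0. A first test of free RNA went against it, since more free RNA without exercise would raise markers of other classes without exercise. Those markers were instead higher with exercise in 7 of 7 classes (medians 0.13 to 0.60), and above the median of all genes in 5 of 7 (-0.04 to 0.46). That test covers the markers and does not measure free RNA of both lists, so it does not decide. Over all kept nuclei, Ttr had 11228 UMIs without exercise against 28 with it and Hbb-bs 1360 against 45. Mitochondrial genes took 0.035% against 0.020% of kept UMIs. Of the other choroid plexus genes, Folr1 had 61 against 8 UMIs, Kcnj13 247 against 37 and Clic6 115 against 71, whereas Kl had 434 against 594. Apart from Kl, the values of these genes go with more free RNA without exercise but do not measure that of both lists. Free RNA, an effect of running and differences between animals or preparations all stay open.

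Interferon response genes were higher in microglia of the knock-in with exercise than without it. Neuronal RNA in the class is argued against, since with exercise 6 of 6 measured members stood above their highest CPM in the 4 neuron classes, with a lower counting bound of 4.26 for the median log2 ratio, and microglia markers, which dilution would lower alike, were at 3736 CPM with and 3003 without exercise. A trend with gene length is argued against by a percentile of 99.99 among length-matched lists. RNA of astrocytes, whose markers were at 397 against 173 CPM, was not tested. Running is among the open explanations and was not tested, as are differences between animals or preparations.

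Disease-associated microglia genes were higher in the knock-in without exercise than in WT without exercise. Neuronal RNA is argued against, since in the knock-in 16 of 17 members stood above their highest CPM in the 4 neuron classes, with a lower counting bound of 3.08 for the median log2 ratio, while microglia markers were at 3003 CPM against 3274 in WT, and gene length is argued against by percentile 100 of length-matched lists. Free RNA of other cells cannot be told apart from higher levels in microglia: with each member's UMIs per nucleus in the highest of the 6 other classes taken off the knock-in microglia, the lower counting bound was -1.96, and with those of the lowest class the median was 0.73 (0.50 to 1.36). In both cases nothing was taken off the WT microglia, which can only lower the median, so the bound of -1.96 is not evidence for free RNA. The levels in other classes include their own expression, which keeps this open, and a restriction to members with a class CPM at least that over all nuclei, tried first, left out none of the 17 members. An effect of the knock-in is among the open explanations and was not tested.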

How the results depend on the processing

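The alternative of at least 1200 UMIs was chosen after the data were seen, and the others before. No paired analysis was possible because each group had 1 library and no result came from a test. For 298 reported results 3350 alternative values were computed, of which 2798 lay within the counting interval of the reported value, 513 outside it and 39 had the opposite sign where that interval left out 0. Of the list medians with an interval without 0, 91.6% (no doublets left out) to 100% (resolution 0.5) kept their sign. Recovery of known ratios was simulated at the observed class totals in granule neurons, microglia and astrocytes alone, with no differences between libraries beyond Poisson counting. For genotype without exercise, 84% of 50 genes with an absolute log2 ratio of 1 had the right sign and an interval without 0 in microglia and 60.5% of 43 genes in astrocytes, and for exercise in the knock-in 98% of 50 genes in granule neurons. All values of opposite sign in that sense, and those outside the interval for the main results, follow by setting as log2 ratios unless stated, and the cause was not tested. Of the other results, values outside the interval are counted above and stand beside some of them.

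With at least 1000 genes per nucleus, disease-associated microglia genes had 0.78 for genotype without exercise and 0.88 for exercise in the knock-in, interferon genes in microglia 2.77 for the latter, and disease-associated oligodendrocyte genes -0.018 for genotype without exercise. Shares gave 0.064 (genotype without exercise) and 0.023 (exercise in the knock-in) for granule neurons, -0.14 and 1.68 for microglia, -1.54 and 2.04 for oligodendrocytes, and -0.85 for oligodendrocytes with exercise in WT. With at least 1200 UMIs, shares for exercise in the knock-in gave 0.12 for granule neurons, 1.33 for microglia and 0.43 for oligodendrocytes, and -0.21 for oligodendrocytes and genotype without exercise. Over nuclei of named classes alone, granule neurons had -0.013 for genotype without exercise and 0.086 for exercise in WT.

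With no doublets left out, disease-associated microglia genes had -0.44 (exercise in WT), -0.34 (exercise in the knock-in) and 0.66 (genotype with exercise). Interferon genes in microglia had 0.37, 1.47 and 0.55 in that order. Homeostatic microglia genes had 0.039 for exercise in WT and -1.40 for genotype with exercise, complement 0.072 and microglial ribosomal genes 0.28 for exercise in WT, and homeostatic astrocyte genes 0.20 for exercise in the knock-in. For genotype without exercise granule neurons had 0.45 for OXPHOS and 0.37 for ribosomal genes. Microglia shares had -1.57 and 1.30 for exercise in WT and in the knock-in.

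At resolution 2.0, disease-associated microglia genes had -0.066 (exercise in WT), -0.31 (exercise in the knock-in) and 0.78 (genotype with exercise), and interferon genes in microglia 0.25, 1.55 and 0.75. Homeostatic microglia genes had -1.33 for genotype with exercise and disease-associated astrocyte genes 0.14 for genotype without exercise. For exercise in WT, astrocytes had -0.027 for OXPHOS and -0.035 for ribosomal genes and -0.26 for Mbp, and microglia 0.22 for ribosomal genes. Granule neurons had 0.44 for OXPHOS and 0.39 for ribosomal genes for genotype without exercise. Microglia shares had -1.58 and 1.32 for both exercise contrasts. At resolution 0.5, disease-associated microglia genes had 0.58 for exercise in the knock-in.

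With 4000 variable genes, exercise in the knock-in gave -0.028 for disease-associated and 1.59 for interferon genes in microglia and 0.42 for clock genes in CA1 neurons. Exercise in WT gave -0.23 for immediate early, -0.52 for clock and 0.15 for ribosomal genes in CA1 neurons, -0.21 for OXPHOS genes in granule neurons and 0.22 for the share of oligodendrocyte precursors. Cholesterol genes in CA1 neurons had 0.75 for genotype with exercise. Genotype without exercise gave 0.43 for OXPHOS and 0.38 for ribosomal genes in granule neurons and -0.76 for Dpp10 in astrocytes.

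With equal weight per nucleus, disease-associated microglia genes had -0.27 (exercise in WT), -0.16 (exercise in the knock-in) and 1.56 (genotype with exercise), homeostatic microglia genes -0.43 for the last, interferon genes in microglia 1.58 for exercise in the knock-in, disease-associated astrocyte genes 0.14 for genotype without exercise and CA1 cholesterol genes 0.76. Thinned to 1500 UMIs, disease-associated microglia genes had 0.67 and 1.39 for genotype without and with exercise, homeostatic ones -0.097 for the latter, interferon genes in microglia 0.54 for exercise in WT and 1.34 for genotype with exercise, immediate early genes in CA1 neurons -0.012 and granule OXPHOS genes -1.37 for exercise in the knock-in, and glucocorticoid genes in granule neurons 0.012 for exercise in WT.

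With TMM factors, CA1 neurons had 0.64 for cholesterol genes (genotype with exercise) and -0.24 for clock genes (exercise in WT). Granule neurons had 0.067 for glutamatergic synapse, -0.067 for OXPHOS and -0.23 for ribosomal genes for exercise in WT and -1.32 for OXPHOS genes for exercise in the knock-in. Median-of-ratios factors gave 0.64, -0.21, 0.087, -0.048, -0.21 and -1.29 for the same results and -0.35 for the unfolded protein response in CA1 neurons for exercise in WT. With a total without mitochondrial and the 50 highest genes, CA1 cholesterol genes had 0.76. In granule neurons exercise in the knock-in then gave -0.0056 for neurotrophic, -0.020 for glutamatergic, -1.38 for OXPHOS, -1.43 for ribosomal and 0.27 for clock genes. Exercise in WT gave 0.028 for glutamatergic and -0.11 for OXPHOS genes, and genotype without exercise 0.053 for GABAergic, 0.74 for OXPHOS and 0.73 for ribosomal genes.

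Over members with a class CPM at least that over all nuclei, granule neurons had 0.048 for OXPHOS, 0.28 for ribosomal and 0.039 for clock genes for genotype without exercise, and -0.45, -0.80 and 0.096 for exercise in the knock-in. Clock genes had 0.71 in CA1 neurons and -0.020 in oligodendrocytes for exercise in the knock-in. Over members with at least 200 UMIs, disease-associated microglia genes had 0.75 for genotype without exercise, disease-associated oligodendrocyte genes 0.027 and 0.020 for genotype without and with exercise, and immediate early genes in CA1 neurons -0.26 for exercise in the knock-in. Without a UMI minimum, interferon genes in inhibitory neurons had -0.17 for exercise in the knock-in.

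Over genes with at least 500 UMIs, the correlations of both exercise contrasts were -0.23 in granule, -0.30 in CA1, -0.29 in CA3 and -0.18 in inhibitory neurons, -0.34 in oligodendrocytes, -0.16 in astrocytes and -0.28 in microglia. Those of both genotype contrasts were -0.46, -0.48, -0.52, -0.46, -0.59, -0.13 and 0.16.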

Other observations

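The gene levels, shares and correlations given here were chosen after they were seen.

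Some genes stood apart in 1 library in all 4 neuron classes. Gas5 was lowest in WT with exercise, at 24.7 CPM in CA1 neurons against 73.0, 65.8 and 72.0 in WT without exercise, knock-in without exercise and knock-in with exercise. Rgl2 was lowest in the knock-in without exercise, at 8.01 CPM in granule neurons against 37.0 in WT without, 21.8 in WT with and 33.3 in knock-in with exercise. P2ry14 was lowest in the knock-in with exercise, at 14.8 CPM in inhibitory neurons against 72.3, 87.7 and 185 in WT without, WT with and knock-in without exercise. Catspere1 was highest in the knock-in with exercise, at 55.1 CPM in CA3 neurons, and at most 0.905 in the other libraries. Tmem163 was lower in both knock-in libraries, with 12.1 and 7.64 CPM in inhibitory neurons of the knock-in without and with exercise and 98.7 and 64.3 in WT. In oligodendrocytes Tmem163 stood at 66.7 and 72.5 CPM in the knock-in and 189 and 160 in WT.

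Of the 24 values of named genes for exercise in the knock-in, 22 had the same direction in at least 4 of 5 other classes, as did 22 of 24 for genotype without exercise and 19 of 24 for exercise in WT. In each contrast the 24 values came from 17 different genes, some named in several classes that then count among the other classes. All classes of a contrast come from the same pair of libraries, and no such share was computed over all genes, so these counts are a description only. Of the 46 different named genes, 7 lie on chromosome 1. Rad51ap2 stood at 47.6 against 14.4 CPM in granule neurons for genotype without exercise, and Ndst4, a heparan sulfate enzyme, at 204 against 52.1 in oligodendrocytes. Mt3, a metallothionein, stood at 82.5 against 39.1 CPM in oligodendrocytes for exercise in WT. Wdr17 stood at 303 against 1514 CPM and Nnat, an imprinted gene, at 163 against 822 in astrocytes for exercise in the knock-in, and Nnat overlaps Blcap on the other strand.

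Smaller classes also had different shares. Cajal-Retzius cells, an early-born neuron type, made up 0.578% (0.440 to 0.745) of WT without, 0.476% of WT with, 1.06% of knock-in without and 0.778% of knock-in with exercise. CA2 neurons made up 1.13%, 1.15%, 1.25% and 0.698% (0.534 to 0.895) in that order, and committed oligodendrocyte precursors 0.157%, 0.0768%, 0.162% and 0.297%. Unnamed cluster 16, low in UMIs, held 630 nuclei, of which 502 came from the knock-in with exercise. Log2 ratios followed gene length across genes in oligodendrocytes, with Spearman correlations of -0.53 for genotype without exercise and 0.58 for exercise in the knock-in, which share a library. Over the 7 classes the correlation ran from -0.53 to -0.13 for genotype without exercise, from -0.04 in astrocytes to 0.36 in CA3 neurons for exercise in WT, from 0.08 in CA3 neurons to 0.58 for exercise in the knock-in, with 0.35 in astrocytes, and from -0.29 in microglia to 0.35 in oligodendrocytes for genotype with exercise.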
